A study of Mus musculus with 18 samples.

How the data were processed

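RNA from isolated mouse brain endothelial cells was sequenced in 18 libraries prepared with a stranded mRNA kit. The animals carried floxed Pdcd10 alleles (Pdcd10 encodes CCM3, a scaffold protein whose loss causes cerebral cavernous malformations), and 4-hydroxytamoxifen (50 µg) was given at postnatal day 1. In the group named KO, the Slco1c1-iCreERT2 driver deleted Pdcd10 in brain endothelium. The group named flox had no driver, although the design text also mentions uninjected driver animals as controls and does not say which libraries, if any, came from them. An astrocyte reporter (Aldh1l1-EGFP/Rpl10a) was part of the genotype. Cells were taken at postnatal day 57, after 7 days in 12% oxygen (hypoxia) or in room air at 21% oxygen (normoxia).

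The authors aligned the reads with HISAT2 to GRCm39 and used edgeR, without giving versions or counting parameters. The deposited read counts are whole numbers for 57010 Ensembl genes in the 18 libraries. The deposited RPKM (reads scaled by library total and gene length) carry 1 decimal. For the 1453 genes above 20 RPKM in every library, the ratio of count share to RPKM implied 1 length per gene to within 0.446%, so the RPKM were scaled by column totals alone. Total counts ran from 17.9 to 31.2 M per library. The reference at hand was the GRCm38 annotation (GENCODE M21), which served for gene symbols only, so no coordinates are given; 91.1% of the identifiers had a symbol there, and those without one held 0.725% of all counts. The strand setting used in counting is not stated, so overlapping antisense genes, and close paralogs such as the H2 genes, Serpina1b and Serpina1d, or the globins, are less certain than other genes.

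Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given, which left 17531 genes, 17160 of them with a symbol. Libraries were scaled by TMM, and all 18 were fitted in 1 model of the 4 groups with robust dispersion estimates and the quasi-likelihood F test (glmQLFit, robust, legacy=FALSE). P values were adjusted by Benjamini-Hochberg within each comparison, at a threshold of 0.05. The 4 comparisons were KO minus flox in normoxia, KO minus flox in hypoxia, and hypoxia minus normoxia in flox and in KO. An interaction contrast tested whether the genotype difference changed with oxygen. Standard errors are the log2 fold change divided by the square root of F. CPM, counts scaled by library size, use the TMM-scaled totals, with a prior count of 2 on the log2 scale.

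A set of 35 gene lists was tested with camera (limma 3.58.1, preset correlation 0.01, on voom values), adjusted over the lists, with camera's estimated correlation and fry as alternatives. For each list, the members passing the gene test were counted over all genes and again with p values adjusted over the list alone. Mean log2 CPM per library of each list was also compared between groups by an exact two-sided permutation test, chosen after the data were seen. The smallest p this test can give is 0.00794 for KO against flox and between the KO groups, and 0.0286 between the flox groups.

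The lists, the comparisons, the alternatives and the rule for naming genes were set before the data were examined, except where stated. The rule names Pdcd10 and 9 further genes of cavernous malformation, inflammation and hypoxia biology; the 8 highest and 8 lowest fold changes per comparison among passing genes with an average log2 CPM of at least 1 and no overlap between the libraries of the groups, leaving out unnamed gene models; up to 4 passing members per list with the smallest adjusted p; and, for the interaction, up to 5 genes per direction and every passing list member. The text prints a selection of these.

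The alternatives were RLE scaling; no filter on low counts, or a stricter one (1 CPM in 4 libraries); DESeq2 1.42.0; the legacy quasi-likelihood fit; only the 2 groups compared; limma-trend on RPKM with 0.1 added; the replicate number as a block; the first principal component of non-endothelial markers, or a sex signal (Y-linked genes against Xist), as a covariate; and leaving out each library in turn. Chosen after the data were seen were leaving out the 2 libraries with neuron markers, leaving out the 3 libraries with both Xist and Y-linked counts, the immediate early gene score as a covariate, this covariate without the 2 neuron-marker libraries, and a block over the normoxia pairs. The last of these also left out the normoxia libraries outside the pairs, normoxia flox 3 and normoxia KO 5 and 6. A value not past the threshold in either fit was counted as unchanged whatever its sign; 18 of the 43 named genes and 64 of the 100 list values that did not pass changed sign in at least 1 alternative.

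Labels number the replicates without saying whether equal numbers belong together. Deviations from the group means were correlated across genes, which are not independent replicates, and the normoxia pairs 1, 2 and 4 gave r of 0.579, 0.294 and 0.847. Of the 21 pairs with equal numbers, 7 exceeded 0.1. The mean r was -0.012 for equal numbers and 0.018 for unequal ones. Of the 18 libraries, 5 correlated best with a library of their own number in another group. Pair 4 is made of the libraries with neural RNA, and normoxia flox 2 correlated more with normoxia KO 6 (0.392) than with normoxia KO 2. Equal numbers are thus not shown to be pairs, and the word pair below means equal numbers only. The method was tested on simulated data with the same group sizes: genes simulated with 2-fold changes were recovered in 46.3% to 58.2% of cases in the 4 comparisons and in 20.9% for the interaction, genes with 4-fold changes in 69.7% to 78.8% and in 51.5%, and 4.39% to 10.7% of the calls were false. In these simulations 17311 to 17314 of 17531 genes were unchanged, and genes varied independently, without neural RNA, sex or dissociation differences. The rates therefore need not hold for the real data. No library was left out of the comparisons, and no correction for sex, dissociation or other cell types was applied unless named.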

Results

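Transcripts were counted in isolated brain endothelial cells from 4 groups of mice at postnatal day 57. There were 4 flox and 5 KO libraries in normoxia, and 4 flox and 5 KO libraries after hypoxia. The mean total count per library was 21.5 ± 2.05 M (SD, n = 4) for normoxia flox, 25.5 ± 4.17 M (SD, n = 5) for normoxia KO, 20.3 ± 2.05 M (SD, n = 4) for hypoxia flox and 20.8 ± 2.19 M (SD, n = 5) for hypoxia KO. Changes below are log2 fold changes ± SE from the edgeR quasi-likelihood model of all 18 libraries, with Benjamini-Hochberg adjusted p values, unless another measure is named. Libraries are called by group and replicate number. The name of the series sets the purpose: an inflammatory signature of cavernous malformation disease in normoxia and in hypoxia.

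The endothelial genes Pecam1 and Cldn5 were abundant in every library, between 1044 and 1874 CPM for Pecam1 and between 1329 and 2374 CPM for Cldn5 (shares of the column total). A pair of libraries carried neural RNA: Syt1, a synaptic vesicle protein gene, stood at 848 CPM in normoxia flox 4 and 465 CPM in normoxia KO 4, against at most 8.93 CPM in any other library. Fos, an immediate early gene that responds within minutes to tissue dissociation, ranged from 241 CPM in hypoxia flox 5 to 5413 CPM in normoxia KO 2. It was at 3177 CPM or more in normoxia flox 1, normoxia KO 1, 2 and 5, hypoxia flox 2 and hypoxia KO 2 to 5, and at 1402 CPM or less in the rest. The labels give no sex. All 4 hypoxia flox libraries had Y-linked transcripts and almost no Xist, the RNA that silences an X chromosome in females, while 4 of the 5 hypoxia KO libraries had Xist and almost no Y-linked transcripts. Normoxia flox 3, normoxia flox 4 and normoxia KO 4 had both. The other normoxia libraries divided between both patterns within each genotype.

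**Figure D1:**
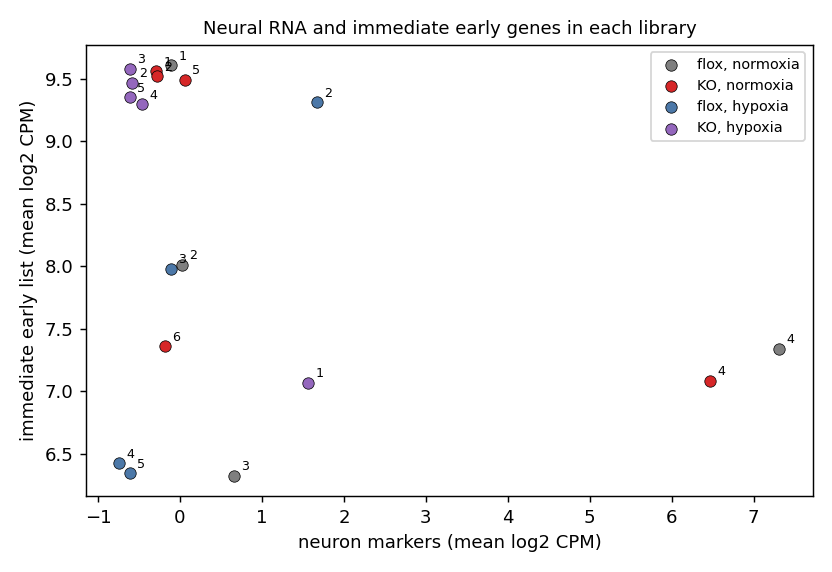
Mean log2 CPM of neuron markers (horizontal axis) against that of immediate early genes (vertical axis), with 1 point per library, coloured by group and labelled by replicate number. Normoxia flox 4 (7.32) and normoxia KO 4 (6.47) lie apart in neuron markers, and immediate early genes divide libraries within groups.

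KO was first compared with flox in normoxia, which asks how endothelial preparations of KO mice differ in room air. Pdcd10 itself (ENSMUSG00000027835) stood at 18.6 ± 1.90 CPM (SD, n = 5) in KO and 39.3 ± 6.14 CPM (SD, n = 4) in flox, a change of -1.08 ± 0.14 (adjusted p = 5.02e-05). Transcripts for coagulation and fibrinolysis, angiogenic growth and the cell cycle were higher in the KO preparations, and arterial and contractile transcripts were lower. The test called 2905 genes, 1673 higher and 1232 lower, and over all 17531 genes tested 14.7% had no overlap between the libraries of the groups, against 1.59% by chance alone. At least 2-fold changes made up 673 of the higher and 474 of the lower calls. Thbd, the gene of the anticoagulant receptor thrombomodulin, rose by 1.40 ± 0.13 (adjusted p = 1.92e-06). The flow-responsive transcription factor genes Klf2 and Klf4, linked to cavernous malformation, had values of 0.89 ± 0.35 (adjusted p = 0.0922) and 0.86 ± 0.61 (adjusted p = 0.397). Klf2 passed without normoxia flox 1 (1.27 ± 0.34, adjusted p = 0.023) and without normoxia KO 4 (1.04 ± 0.33, adjusted p = 0.0392), with DESeq2 (adjusted p = 0.0494), and with the immediate early score as a covariate (0.58 ± 0.14, adjusted p = 0.00776).

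**Figure D2:**
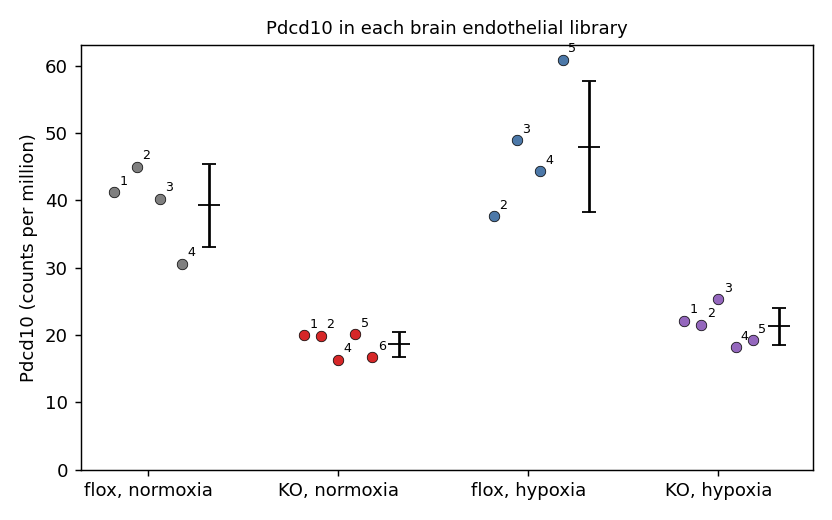
Pdcd10 in CPM (vertical axis, from 0) in each library, with 1 point per library labelled by replicate number and bars for the group mean ± SD. The KO means of 18.6 and 21.3 CPM lie below the flox means of 39.3 and 48.0 CPM, and no KO library overlaps a flox library.

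Among the highest changes in normoxia KO were Ms4a8a, a membrane-spanning protein gene (5.79 ± 0.61, adjusted p = 8.63e-07), Gpr35, a G protein-coupled receptor gene (4.75 ± 0.50, adjusted p = 7.38e-06), Fndc1 (4.54 ± 0.49), Bpifb1 (4.29 ± 0.56), Serpina1b, an alpha-1-antitrypsin gene (4.12 ± 0.79), and the metalloprotease gene Adam33 (4.10 ± 0.59). Egln3, the oxygen sensor that marks hypoxia-inducible factor for degradation, stood 4.17 ± 0.49 higher (adjusted p = 2.21e-05), though DESeq2 returned no adjusted p for it. Among the lowest were Gkn3 (-3.78 ± 0.50, adjusted p = 7.14e-05), the olfactory receptor gene Olfr78 (-3.46 ± 0.32), the cytokine receptor gene Csf2rb2 (-3.42 ± 0.51), Syt15 (-3.03 ± 0.29), Susd5 (-2.98 ± 0.40), Asb2 (-2.95 ± 0.37) and the monooxygenase gene Fmo2 (-2.85 ± 0.25, adjusted p = 1.15e-06).

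The arterial list fell in normoxia KO: 12 of its 20 members passed, all lower, or 14 when adjusted over the list alone, with a median of -1.03. Its camera adjusted p was 1.07e-11, or adjusted p = 0.0509 with an estimated correlation, and the exact permutation test of its mean level gave an adjusted p of 0.0463. Hey1, a Notch effector, changed by -1.92 ± 0.22, the arterial kinase gene Bmx by -1.69 ± 0.20 and the gap junction gene Gja5 by -2.21 ± 0.28. Smooth muscle markers moved the same way: 8 of 11 fell and 1 rose, over all genes and adjusted over the list alone, with a median of -1.76 (camera adjusted p = 6.66e-06, adjusted p = 0.35 with an estimated correlation, exact permutation adjusted p = 0.0463). Acta2, the smooth muscle actin gene, stood at -2.34 ± 0.23, the myosin gene Myh11 at -2.45 ± 0.30, Tpm2 at -2.03 ± 0.21 and Mylk at -1.95 ± 0.19. Pericyte markers went the other way, with 3 of 13 higher and none lower, 4 adjusted over the list alone, at a median of 0.55 (adjusted p = 0.0192, adjusted p = 0.86 with an estimated correlation). The channel gene Kcnj8 rose by 3.16 ± 0.46 and the peptidase gene Anpep by 1.66 ± 0.32. The pericyte call was lost without normoxia flox 3 (median 0.30, adjusted p = 0.0931) and without normoxia flox 4 (median 0.30, adjusted p = 0.0794). It was also lost with a block over the normoxia pairs 1, 2 and 4 without the other normoxia libraries (median 0.34, adjusted p = 0.101), though not with the replicate number as a block over all groups (median 0.69, adjusted p = 0.00417). Its mean level was higher in KO in all 3 pairs. The exact permutation test gave an adjusted p of 0.0926.

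The coagulation and fibrinolysis list holds clotting factors as well as anticoagulants, so its rise gives no net direction of clotting. Its genes rose in normoxia KO: 10 of 19 were higher and none lower, 11 adjusted over the list alone, at a median of 1.37. This list kept its call with an estimated correlation (camera adjusted p = 2.86e-08, adjusted p = 0.0281 with an estimated correlation). Coagulation factor V, F5, rose by 3.24 ± 0.18 (adjusted p = 2.53e-08), Tfpi, the inhibitor of the tissue factor pathway, by 1.63 ± 0.10, Anxa2, a plasminogen-activating annexin, by 1.65 ± 0.11, and the protein C receptor gene Procr by 1.40 ± 0.18. Tip cell genes of sprouting vessels rose as well, 12 of 22 higher and 3 lower, 14 and 3 adjusted over the list alone, at a median of 0.95 (camera adjusted p = 5.06e-07, adjusted p = 0.0509 with an estimated correlation). Angpt2, a vessel-destabilizing ligand, was up by 2.41 ± 0.23, Trp53i11 by 2.20 ± 0.26, and the basement membrane genes Nid1 and Nid2 by 1.01 ± 0.11 and 1.08 ± 0.13. Both lists had an exact permutation adjusted p of 0.0463.

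Although the oxygen was that of room air, 13 of 35 targets of hypoxia-inducible factor were higher in KO and 1 lower, with equal counts adjusted over the list alone and a median of 0.28 (camera adjusted p = 7.04e-05, adjusted p = 0.153 with an estimated correlation, exact permutation adjusted p = 0.0463). The lactate exporter Slc16a3 rose by 3.09 ± 0.35, Pdk1, which diverts pyruvate from mitochondria, by 1.12 ± 0.11, and Mxi1 by 0.80 ± 0.10. Vegfa had a value of 0.80 ± 0.42 (adjusted p = 0.232). The glucose transporter gene Slc2a1 had one of 0.23 ± 0.14 (adjusted p = 0.285). In glycolysis, 7 of 17 members rose and none fell, 10 adjusted over the list alone, at a median of 0.50 (camera adjusted p = 1.64e-05, adjusted p = 0.705 with an estimated correlation, exact permutation adjusted p = 0.581). Ldha was up by 0.76 ± 0.09, Pfkl by 0.88 ± 0.11 and Hk1 by 0.62 ± 0.10. Cell proliferation genes rose in 22 of 30 members and fell in none, 27 adjusted over the list alone, at a median of 1.63 (camera adjusted p = 5.77e-13, adjusted p = 0.327 with an estimated correlation, exact permutation adjusted p = 0.0463). The mitotic kinase gene Cdk1 was up by 2.56 ± 0.32, Ube2c by 2.75 ± 0.35, Ccnb2 by 2.30 ± 0.30 and Cdc20 by 1.55 ± 0.17.

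The inflammation and leukocyte adhesion list had 2 members higher and 1 lower of 25 in normoxia KO, over all genes and adjusted over the list alone, with a median of 0.61 (camera adjusted p = 0.165). It passed without normoxia flox 1 (median 0.95, adjusted p = 0.0421) and without normoxia KO 4 (median 0.64, adjusted p = 0.0423). Ccl5, a chemokine for T cells, was up by 3.36 ± 0.88 (adjusted p = 0.0127), a call lost with the block over the normoxia pairs (adjusted p = 0.121). The adhesion molecule genes Vcam1 and Icam1 had values of 0.62 ± 0.34 (adjusted p = 0.259) and 0.98 ± 0.91 (adjusted p = 0.533), and the prostaglandin synthase gene Ptgs2 had -0.94 ± 0.89 (adjusted p = 0.541). Cx3cl1, the chemokine fractalkine, had a value of 0.25 ± 0.27 (adjusted p = 0.593). It reached 0.70 ± 0.19 (adjusted p = 0.018) without normoxia flox 4, one of the libraries with neural RNA, and 0.52 ± 0.16 (adjusted p = 0.0318) without both.

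NF-kB targets rose in 5 of 20 members in normoxia KO and fell in none, over all genes and adjusted over the list alone, at a median of 0.75 (camera adjusted p = 0.00202, adjusted p = 0.725 with an estimated correlation). Traf1 was up by 1.55 ± 0.18, Nfkbie by 1.27 ± 0.18, and Relb and Cd40 by 0.88 ± 0.16 and 0.44 ± 0.08. The list of genes tied to CCM endothelium, with Klf2 and Klf4, had 7 of 26 higher and 1 lower, in equal numbers adjusted over the list alone, at a median of 0.61 (camera adjusted p = 0.00711, adjusted p = 0.505 with an estimated correlation). The median fell to 0.19 (adjusted p = 0.0909) with the immediate early score as a covariate. Lymphocyte markers were higher in 5 of 16 and lower in none, 8 adjusted over the list alone, at a median of 1.62 (camera adjusted p = 0.00187, adjusted p = 0.725 with an estimated correlation), including Cd2, a T cell adhesion molecule (2.43 ± 0.40), and Igkc, an antibody light chain (1.82 ± 0.40). Antigen presentation by MHC class II had 3 of 8 higher, 4 adjusted over the list alone, at a median of 1.62 (camera adjusted p = 0.0693). It passed without normoxia flox 2 (median 1.73, adjusted p = 0.0489), normoxia flox 4 (2.46, adjusted p = 0.048) or normoxia KO 6 (1.78, adjusted p = 0.0183). Its member calls did not hold, however. Without normoxia flox 1 or normoxia flox 3, Cd74, H2-Aa and H2-Ab1 did not pass (adjusted p = 0.0517 to 0.113). Cd74 was also lost without normoxia flox 2, normoxia flox 4 or normoxia KO 1, 2 or 5 (adjusted p = 0.0506 to 0.0788). With the block over the normoxia pairs none of the 8 passed (median 1.51, adjusted p = 0.136), although the mean level was higher in KO in all 3 pairs. The list passed with the replicate number as a block over all groups (2.22, adjusted p = 0.0478, 2 members higher), with the sex signal as a covariate (1.63, adjusted p = 0.012, 4 higher), without a filter, with DESeq2 and with only the 2 groups fitted. None of these lists passed the exact permutation test. Its adjusted p was 0.321 for NF-kB targets, 0.152 for the CCM list, and 0.0926 for lymphocyte markers and for MHC class II.

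A block over the normoxia pairs 1, 2 and 4 alone left 1751 genes with Pdcd10 at -1.07, against 2905 with all libraries and no block. This fit left out normoxia flox 3 and normoxia KO 5 and 6, so the block and the smaller groups cannot be told apart as reasons for lost calls. The exact permutation test takes no account of these pairs, which the labels do not establish as pairs. With the block, camera still called glycolysis (median 0.52, adjusted p = 1.28e-06), NF-kB targets (0.53, adjusted p = 0.00308), the CCM list (0.39, adjusted p = 0.0196) and lymphocyte markers (1.62, adjusted p = 0.00046). The mean level of each of these lists was higher in KO in all 3 pairs. In none of the 4 comparisons, nor in the interaction, did camera call more lists than random regroupings of the libraries often did, so a single list call carries less weight than the gene counts.

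**Figure D3:**
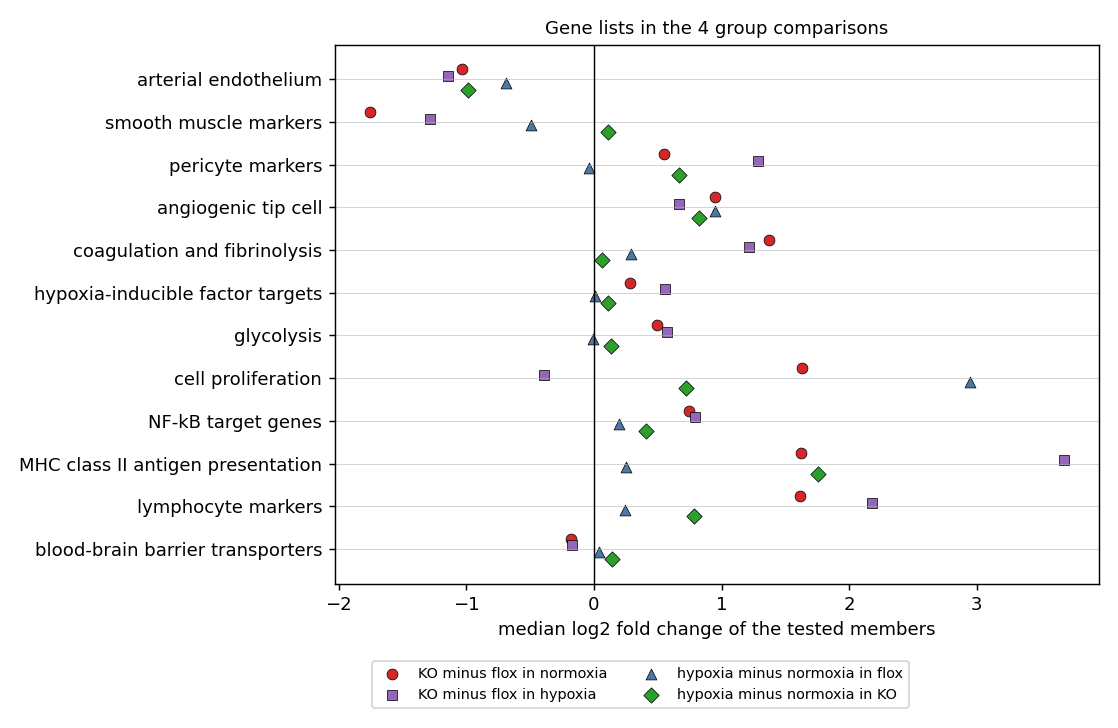
Median log2 fold change (horizontal axis) of the tested members of 12 gene lists (vertical axis) in the 4 comparisons, with 1 symbol per comparison and no error drawn. Arterial genes are below 0 in all 4, and proliferation genes range from -0.39 for KO against flox in hypoxia to 2.95 for oxygen in flox.

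The same genotype comparison after 7 days of hypoxia asks whether low oxygen changes the difference. Pdcd10 was at 21.3 ± 2.77 CPM (SD, n = 5) in KO and 48.0 ± 9.79 CPM (SD, n = 4) in flox (-1.17 ± 0.14, adjusted p = 2.87e-05). Arterial and contractile genes were again lower, and coagulation, tip cell, antigen presentation, pericyte and leukocyte genes were higher. The test called 3916 genes, 1994 higher and 1922 lower, and 22.3% of all genes tested had no overlap between groups (1.59% by chance). Immediate early genes nearly followed genotype here, at a mean log2 CPM of 9.30 to 9.58 in hypoxia KO 2 to 5 and 6.35 to 7.98 in hypoxia flox 3 to 5. Hypoxia KO 1 (7.07) and hypoxia flox 2 (9.32) went the other way. The sex signal nearly followed genotype too, so dissociation and sex are hard to set apart from genotype for single genes. Klf2 rose by 1.41 ± 0.35 (adjusted p = 0.00947), Thbd by 1.35 ± 0.13 (adjusted p = 4.51e-06) and Cx3cl1 by 1.03 ± 0.28 (adjusted p = 0.0139). Klf4 had a value of 1.5 ± 0.63 (adjusted p = 0.0994), Vcam1 0.64 ± 0.34 (adjusted p = 0.208), Icam1 0.85 ± 0.90 (adjusted p = 0.553), Ptgs2 0.10 ± 0.89 (adjusted p = 0.956) and Slc2a1 0.25 ± 0.14 (adjusted p = 0.214). Vcam1 passed without hypoxia flox 2 (adjusted p = 0.0401). Vegfa, the main vascular growth factor, had a value of 1.20 ± 0.43 (adjusted p = 0.0553) and passed without hypoxia flox 2 (1.65 ± 0.44, adjusted p = 0.0155) and without hypoxia KO 1 (1.35 ± 0.43, adjusted p = 0.0323), and with DESeq2 (adjusted p = 0.0189).

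Rnase1, a secreted ribonuclease gene, stood highest in hypoxia KO (5.29 ± 0.63, adjusted p = 2.83e-05), followed by Gpr35 (5.16 ± 0.51), Serpina1b (5.04 ± 0.92), Serpina1d (4.58 ± 0.84), the interferon-inducible gene Ifi211 (4.51 ± 0.48) and the T cell co-stimulator gene Tnfrsf9 (4.50 ± 0.81). Gkn3 was again lowest (-4.35 ± 0.53, adjusted p = 4.65e-05), followed by Lao1 (-3.79 ± 0.70), Olfr78 (-3.66 ± 0.36), Syt15 (-3.29 ± 0.29), Coro2a (-2.99 ± 0.24), Foxp2 (-2.87 ± 0.70) and the exchange factor gene Rasgrf2 (-2.86 ± 0.47).

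Inflammatory genes rose in hypoxia KO: 8 of 25 members of the inflammation list were higher and 1 lower, 10 and 1 adjusted over the list alone, at a median of 0.86 (camera adjusted p = 0.0101, adjusted p = 0.658 with an estimated correlation). Il1b, the cytokine interleukin-1 beta, was up by 4.77 ± 1.09 (adjusted p = 0.00589), and the chemokine genes Ccl5 and Ccl9 by 3.07 ± 0.59 and 3.34 ± 0.81. With the immediate early score as a covariate the list's median was 0.37 and its call ended, and immediate early genes themselves had a median of 1.29 in this comparison (camera adjusted p = 0.0011, adjusted p = 0.658 with an estimated correlation). NF-kB targets were higher in 7 of 20 and lower in none, over all genes and adjusted over the list alone, at a median of 0.80 (camera adjusted p = 3.23e-05, adjusted p = 0.438 with an estimated correlation), led by Traf1 (1.35 ± 0.18), Nfkbie (1.25 ± 0.18) and Tnfaip2 (1.94 ± 0.43). The CCM endothelial list had 9 of 26 higher and 1 lower, 11 and 2 adjusted over the list alone, at a median of 1.19 (camera adjusted p = 0.000354, adjusted p = 0.304 with an estimated correlation). None of these lists passed the exact permutation test. Its adjusted p was 0.152 for inflammation, 0.157 for immediate early genes, 0.0877 for NF-kB targets and 0.0521 for the CCM list.

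MHC class II genes, which present antigen to helper T cells, rose in 7 of 8 members, 8 adjusted over the list alone, at a median of 3.68 (camera adjusted p = 0.000932, adjusted p = 0.465 with an estimated correlation, exact permutation adjusted p = 0.0397). H2-Aa was up by 3.85 ± 0.74 (adjusted p = 0.00184), H2-Ab1 by 3.78 ± 0.78, the invariant chain gene Cd74 by 4.01 ± 0.86 and Ciita, the master regulator of the class, by 3.12 ± 0.67. Cd74 stood at 272 CPM in hypoxia KO 4, the only KO library of that group with Y-linked transcripts, and between 14.2 and 40.5 CPM in the other 4. Lymphocyte markers moved with these genes: 13 of 16 rose and none fell, 15 adjusted over the list alone, at a median of 2.18 (camera adjusted p = 7.66e-06, adjusted p = 0.435 with an estimated correlation, exact permutation adjusted p = 0.0521). Igkc was up by 2.34 ± 0.40 and the cytotoxic protease gene Gzma by 3.35 ± 0.71. Neutrophil markers rose in 6 of 8, equally adjusted over the list alone, at a median of 3.07 (camera adjusted p = 0.0256, adjusted p = 0.646 with an estimated correlation). That call was lost without hypoxia flox 2 (median 2.43, adjusted p = 0.0627), hypoxia KO 2 (3.53, adjusted p = 0.0558) or hypoxia KO 4 (1.41, adjusted p = 0.0935). Microglia and macrophage markers rose in 5 of 17 and fell in 1, 6 and 1 adjusted over the list alone, at a median of 1.72 (camera adjusted p = 0.0175, adjusted p = 0.646 with an estimated correlation). Neither the neutrophil nor the microglia and macrophage list passed the exact permutation test (adjusted p = 0.119 and 0.0521).

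Arterial genes fell in 13 of 20 members in hypoxia KO and rose in none, 15 adjusted over the list alone, at a median of -1.15 (camera adjusted p = 1.34e-09, adjusted p = 0.0811 with an estimated correlation). Gja5 changed by -2.73 ± 0.30, Bmx by -2.02 ± 0.20 and Hey1 by -1.64 ± 0.22. Smooth muscle markers fell in 7 of 11 and rose in 1, equally adjusted over the list alone, at a median of -1.28 (camera adjusted p = 0.000225, adjusted p = 0.438 with an estimated correlation), with Acta2 at -1.65 ± 0.23 and Mylk at -1.44 ± 0.19. Pericyte markers rose in 6 of 13 and fell in none, 12 adjusted over the list alone, at a median of 1.29 (camera adjusted p = 1e-06, adjusted p = 0.435 with an estimated correlation). Kcnj8 was up by 4.03 ± 0.47, Abcc9 by 3.70 ± 0.58 and Anpep by 1.87 ± 0.32. The arterial and pericyte lists had an exact permutation adjusted p of 0.0397, and the smooth muscle list 0.0521.

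Coagulation genes rose in 10 of 19 and fell in none, 10 and 1 adjusted over the list alone, at a median of 1.21 (camera adjusted p = 4.37e-06, adjusted p = 0.0811 with an estimated correlation), with F5 up by 2.01 ± 0.17, Anxa2 by 1.26 ± 0.11 and Tfpi by 1.21 ± 0.10. Tip cell genes rose in 11 of 22 and fell in 1, 13 and 2 adjusted over the list alone, at a median of 0.67 (camera adjusted p = 1.7e-05, adjusted p = 0.0825 with an estimated correlation). Angpt2 was up by 1.63 ± 0.22, and Nid1 by 0.67 ± 0.11. Hypoxia-inducible factor targets were higher in 12 of 35 and lower in 3, 19 and 3 adjusted over the list alone, at a median of 0.55 (camera adjusted p = 4.37e-06, adjusted p = 0.0825 with an estimated correlation), including Slc16a3 (3.24 ± 0.35) and Mxi1 (0.99 ± 0.10). Glycolysis genes rose in 10 of 17 and fell in none, 12 adjusted over the list alone, at a median of 0.57 (camera adjusted p = 4.37e-06, adjusted p = 0.456 with an estimated correlation), including Hk1 (0.77 ± 0.10) and Pfkl (0.66 ± 0.11). All 4 lists had an exact permutation adjusted p of 0.0397. Cell proliferation genes had 1 of 30 lower and none higher, none adjusted over the list alone, at a median of -0.39 (camera adjusted p = 0.00173, adjusted p = 0.646 with an estimated correlation). Mesenchymal transition genes had 8 of 20 higher and 3 lower, 9 and 3 adjusted over the list alone, at a median of 0.48 (camera adjusted p = 0.0112, adjusted p = 0.435 with an estimated correlation), with S100a6 up by 4.24 ± 0.51, Postn by 2.99 ± 0.43 and Tgfb2 at -1.21 ± 0.14. Acta2, a member of both this list and the smooth muscle list, was also among the lower genes. The exact permutation test passed for neither the proliferation nor the mesenchymal list (adjusted p = 0.297 and 0.0521). Scaling by column totals instead of TMM shifted the median of all genes by -0.16 in this comparison, and the RPKM, which rest on column totals, shifted it by -0.14. With limma-trend on the RPKM, which changes the measure and the test as well as the scaling, 29.4% of the genes called were higher in KO, against 50.9% with TMM.

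The genotype difference was largely shared between oxygen levels. Of the genes called in normoxia and in hypoxia, 2029 changed in the same direction, 1131 higher and 898 lower, against 190 and 135 if calls were independent, and 11 went opposite ways. F5, Angpt2, Thbd and Procr were among those higher in both, and Gkn3, Olfr78, Gja5 and Acta2 among those lower in both. Over all genes tested, the log2 fold changes had a rank correlation of 0.632, which is across genes and not across independent samples. No library is part of both comparisons.

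Hypoxia was then compared with normoxia in flox mice, which asks how preparations with intact Pdcd10 differ between oxygen levels. Every hypoxia flox library had Y-linked transcripts and almost no Xist, whereas normoxia flox held both patterns and mixed libraries. Sex and the neural RNA of normoxia flox 4 are thus partly mixed with oxygen here. The highest changes in this comparison included many cell cycle genes. The test called 492 genes, 411 higher and 81 lower, and 8.50% of all genes tested had no overlap between groups (2.86% by chance). The chromosomal passenger kinase gene Aurkb rose by 5.63 ± 0.61 (adjusted p = 2.11e-05), Pimreg by 4.98 ± 0.39 (adjusted p = 4.92e-06), the mitotic kinesin gene Kif18b by 4.67 ± 0.43, the proliferation marker Mki67 by 4.62 ± 0.50, the condensin gene Ncapg by 4.48 ± 0.40 and the checkpoint kinase gene Bub1 by 4.44 ± 0.38. Of the cell proliferation list, 26 of 30 members rose and none fell, 27 adjusted over the list alone, at a median of 2.95. Camera gave an adjusted p of 2.17e-51, and the call held at adjusted p = 0.0112 with an estimated correlation. The exact permutation test gave an adjusted p of 0.25 for this list, the smallest that the 4 against 4 libraries produced after adjustment. Among the lower genes, the growth factor binding gene Ccn3 (-1.99 ± 0.39, adjusted p = 0.00692) and the kinase gene Nuak1 (-1.25 ± 0.23, adjusted p = 0.00382) passed whichever library was left out, though Ccn3 did not when only the 2 groups were fitted (adjusted p = 0.0506).

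Tip cell genes rose with hypoxia in flox: 9 of 22 tip cell members were higher and none lower, 12 and 2 adjusted over the list alone, at a median of 0.95 (camera adjusted p = 5.64e-17, held at adjusted p = 0.00204 with an estimated correlation). The nidogen genes Nid2 and Nid1 rose by 1.52 ± 0.14 and 1.23 ± 0.12, the collagen IV genes Col4a2 and Col4a1 by 0.92 ± 0.10 and 0.88 ± 0.10, and Angpt2 by 1.86 ± 0.23. Arterial genes had a median of -0.69 with 1 of 20 lower, 6 adjusted over the list alone (camera adjusted p = 1e-07, adjusted p = 0.194 with an estimated correlation). Of the 35 targets of hypoxia-inducible factor, 3 rose and none fell, 3 and 1 adjusted over the list alone, at a median of 0.01 with a mean of -0.09 (camera adjusted p = 0.46). Stc2, a stress-induced glycoprotein hormone gene, rose by 1.71 ± 0.23, and Pdk1 by 0.56 ± 0.11. Ldha, a member of the glycolysis list and not of this one, rose by 0.47 ± 0.09. Pdk1 and Ldha did not pass when only the 2 groups were fitted (adjusted p = 0.104 and 0.0967). The apelin gene Apln rose by 2.43 ± 0.52 (adjusted p = 0.0146), a call lost without normoxia flox 1 (adjusted p = 0.0554). None of the 10 genes set in advance passed. Thbd was at -0.49 ± 0.13 (adjusted p = 0.0595) and passed without hypoxia flox 2 (-0.64 ± 0.13, adjusted p = 0.0129) and with DESeq2 (adjusted p = 0.0145). Pdcd10 was at 0.29 ± 0.15 (adjusted p = 0.319), Cx3cl1 at -0.77 ± 0.29 (adjusted p = 0.203), Vegfa at -0.16 and Slc2a1 at -0.01.

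In KO mice, hypoxia changed fewer genes: 260, with 125 higher and 135 lower, and 3.83% of all genes tested had no overlap between groups (0.794% by chance). As in flox, nidogen and collagen IV genes rose, with Nid1 up by 0.88 ± 0.10 (adjusted p = 0.00108), Col4a2 by 0.80 ± 0.09 (adjusted p = 0.000992), Col4a1 by 0.74 ± 0.09 and the laminin gene Lama4 by 0.88 ± 0.12. Tip cell genes rose in 9 of 22 members and fell in none, 12 and 1 adjusted over the list alone, at a median of 0.82 (camera adjusted p = 3.69e-17, held at adjusted p = 0.00178 with an estimated correlation). Stc2 was up by 1.22 ± 0.19, Col7a1 by 1.31 ± 0.22 and Gas2l3 by 1.47 ± 0.24. Angpt1, the vessel-stabilizing Tie2 ligand, changed by -2.20 ± 0.30 (adjusted p = 0.00242), Ms4a8a by -2.21 ± 0.39 and the nitric oxide synthase gene Nos1 by -1.79 ± 0.31. With only these 2 groups in the fit, Gas2l3, Ms4a8a and Nos1 did not pass (adjusted p = 0.0616, 0.0504 and 0.0684). Angpt2 was up by 1.07 ± 0.20, Nox4, an oxidase subunit gene, by 1.43 ± 0.26, and the arterial genes Bmx and Sema3g stood at -1.04 ± 0.19 and -1.11 ± 0.20. These last 4 calls were lost without hypoxia KO 2 (adjusted p = 0.0511, 0.0511, 0.0565 and 0.052).

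Arterial genes were lower in 7 of 20 members and higher in none under hypoxia in KO, 11 adjusted over the list alone, at a median of -0.99 (camera adjusted p = 9.14e-08, adjusted p = 0.269 with an estimated correlation). Proliferation genes rose in 2 of 30 and fell in none, 20 adjusted over the list alone, at a median of 0.72 (camera adjusted p = 1.34e-13, adjusted p = 0.382 with an estimated correlation). No MHC class II member passed over all genes, 6 of 8 were higher adjusted over the list alone, and the median was 1.75 (camera adjusted p = 0.000427, adjusted p = 0.524 with an estimated correlation). The inflammation list had 1 of 25 higher and 1 lower, 2 and 1 adjusted over the list alone, at a median of 0.61 (camera adjusted p = 0.00854, adjusted p = 0.894 with an estimated correlation), a call lost without normoxia KO 4 (median 0.33, adjusted p = 0.134) or hypoxia KO 4 (0.42, adjusted p = 0.221). Pdcd10 was at 0.19 ± 0.13 (adjusted p = 0.539) and Cx3cl1 at 0.01 ± 0.25 (adjusted p = 0.991). No list passed the exact permutation test in this comparison, where the smallest adjusted p was 0.139. With the replicate number as a block the count was 43. The count of 260 also moved with single libraries. It was 53 without hypoxia KO 2, 523 without hypoxia KO 1, 147 without normoxia KO 1, 141 without normoxia KO 4, 127 without normoxia KO 5, 106 without normoxia KO 6 and 102 without hypoxia KO 5.

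The oxygen response had 96 calls in common between flox and KO, all in the same direction, 71 higher and 25 lower, against 2.93 and 0.624 if calls were independent. Nid1, Col4a1, Col4a2, Angpt2, Stc2 and Tmsb10 were among the shared higher genes. The rank correlation across genes was 0.474, and the comparisons have no library in common.

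**Figure D4:**
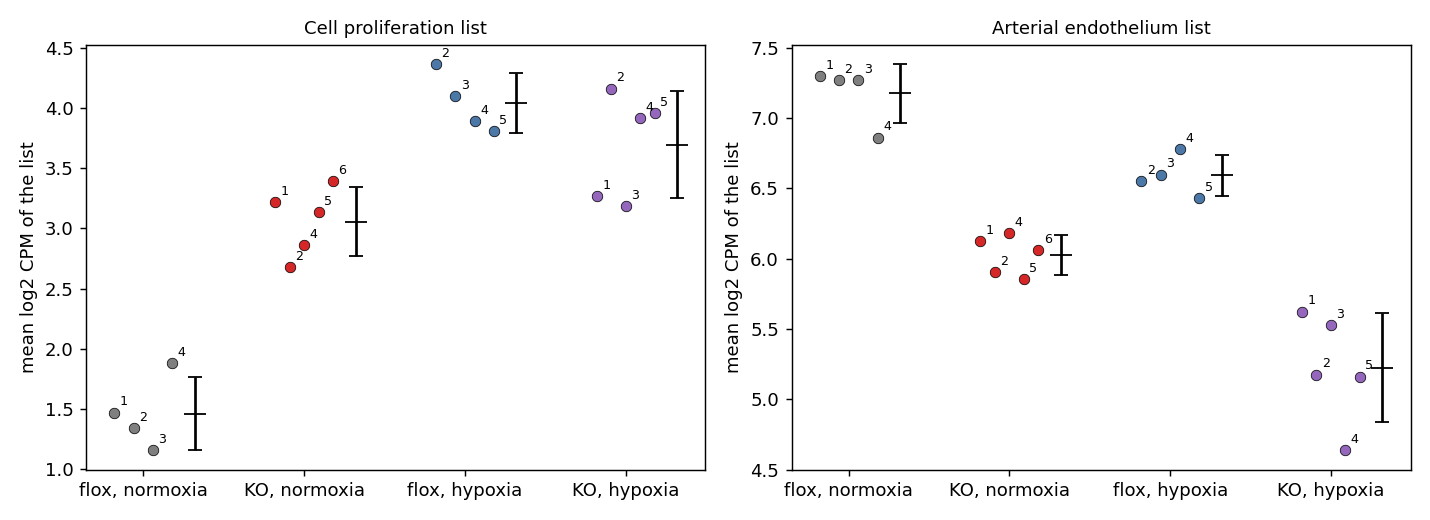
Mean log2 CPM (vertical axes, not from 0) of the proliferation list and of the arterial list in each library, with 1 point per library labelled by replicate number and bars for the group mean ± SD. Proliferation is lowest in normoxia flox, at a mean of 1.46, and the arterial mean falls from 7.17 in normoxia flox to 5.22 in hypoxia KO.

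The interaction asks whether the genotype difference changed with oxygen, and 78 genes passed, all lower and most visibly those of cell division, whereas DESeq2 called 20 of its 145 genes higher. Espl1, the separase gene that parts sister chromatids, had an interaction of -2.85 ± 0.26 (adjusted p = 8.78e-05), Pimreg -4.40 ± 0.48 (adjusted p = 0.000627), Hmmr -3.47 ± 0.44, the DNA methylation cofactor gene Uhrf1 -1.31 ± 0.18 and the kinesin gene Kif20a -2.29 ± 0.32. Of the proliferation list, 18 of 30 members passed, all lower, 25 adjusted over the list alone, at a median of -2.27 (camera adjusted p = 6.22e-48, held at adjusted p = 0.0295 with an estimated correlation). Aurkb was at -4.51, Bub1 at -3.22, Ube2c at -2.93, Cdk1 at -2.81 ± 0.41 (adjusted p = 0.00544) and Ccna2 at -2.66. Proliferation genes were thus at a low level in normoxia flox, with a mean log2 CPM of 1.46, and at 3.06 in normoxia KO, 4.04 in hypoxia flox and 3.70 in hypoxia KO. Cx3cl1 had an interaction of 0.78 ± 0.38 (adjusted p = 0.932) and Klf2 one of 0.51 ± 0.48 (adjusted p = 0.993), so the larger genotype values of these genes under hypoxia were not shown to differ from those in normoxia. With the replicate number as a block, 3 genes passed, Espl1 and Pimreg among them. Leaving out 1 library gave 28 genes without normoxia flox 1, 30 without normoxia flox 2, 38 without normoxia flox 3, 50 without normoxia KO 5, 33 without normoxia KO 6, 34 without hypoxia flox 2, 36 without hypoxia flox 3, 44 without hypoxia flox 4 and 44 without hypoxia flox 5.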

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

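The list permutation tests, the tests with the immediate early score as a covariate, those on other cell types and those that leave out chosen libraries were picked only after the results were seen. The sex covariate was set beforehand as an alternative, but its use to weigh the patterns below was picked after. A library was singled out when its mean log2 CPM over a list lay far from the rest of its group, by Dixon's test at 95%. Total counts and Pdcd10 were tested in the same way. This picked 17 of 148 sets in all, each set being 1 measure in 1 group, where chance picks about 1 in 20 (7.4 of them).

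Hypoxia KO 1 was low in the CCM endothelial list, at a mean log2 CPM of 6.21 against 6.67 to 6.81 in the other 4, and in immediate early genes such as Fos, at 7.07 against 9.30 to 9.58. Hypoxia KO 4 was high in interferon response genes (6.35) and in MHC class I genes (8.12). Normoxia flox 4 was apart in arterial genes (6.86), glycolysis (7.35), astrocyte markers (6.75) and neuron markers (7.32). Normoxia KO 4 was apart in glycolysis (7.49), neuron markers (6.47) and microglia markers (2.45), and hypoxia KO 1 in neuron markers (1.57). Normoxia KO 6 was apart in coagulation genes (4.99) and cholesterol synthesis (4.62), hypoxia flox 5 in junction genes (7.66) and smooth muscle markers (3.54), and normoxia flox 2 in choroid plexus markers (0.41).

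The genotype difference changed with oxygen in 78 genes, each by the interaction test, and the named ones were Espl1 (-2.85), Pimreg (-4.40), Hmmr (-3.47), Uhrf1 (-1.31) and Kif20a (-2.29). Camera called 17 lists for the interaction, and 20 of 60 regroupings of the libraries called as many, up to 27. That number alone is therefore no evidence of an interaction, though these regroupings also mixed the genotypes and cannot decide on it. Besides proliferation (median -2.27, adjusted p = 6.22e-48), the lists called were pericyte markers (0.74, adjusted p = 2.15e-05), venous genes (-0.46 with a mean of 0.09, adjusted p = 0.000221), cholesterol synthesis (0.29, adjusted p = 0.00122), BMP, TGF-beta and Notch targets (0.21, adjusted p = 0.00122), perivascular fibroblast markers (0.88, adjusted p = 0.00159) and neutrophil markers (2.97, adjusted p = 0.00431). Next came interferon response (0.19, adjusted p = 0.00704), MHC class I (0.32, adjusted p = 0.00704), microglia and macrophage markers (2.50, adjusted p = 0.0144), tip cell genes (-0.21, adjusted p = 0.0168), coagulation (-0.047, adjusted p = 0.018), smooth muscle markers (0.51, adjusted p = 0.018), oligodendrocyte precursor markers (0.86, adjusted p = 0.024), immediate early genes (0.44, adjusted p = 0.0301), MHC class II (1.64, adjusted p = 0.041) and mesenchymal transition genes (0.23, adjusted p = 0.0431). With an estimated correlation the proliferation list alone kept its call, and the adjusted p of the other 16 lay between 0.144 and 0.866. The immediate early value turned to -0.44 without normoxia flox 1 (adjusted p = 0.781), and its call was lost without any of 9 other libraries: normoxia flox 2, normoxia KO 4 and 6, hypoxia flox 4 and 5, and hypoxia KO 2 to 5 (adjusted p = 0.0683 to 0.6). The microglia and macrophage value was -0.02 without normoxia flox 4 (adjusted p = 0.479), and the coagulation value 0.18 without hypoxia flox 2 (adjusted p = 0.275). Calls of the interferon, MHC class I, MHC class II, tip cell, mesenchymal, smooth muscle and oligodendrocyte precursor lists were also lost without at least 1 library.

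Other groupings of the libraries tested whether chance could have given counts as large as those reported. Of 60 groupings each, the real one was the 1 grouping with as many calls for KO against flox in normoxia (2905 genes, highest other 2023) and in hypoxia (3916, highest other 2273), for oxygen in KO (260, highest other 2) and for the interaction (78, highest other 2), and likewise for the calls shared by the genotype comparisons (2029, highest other 4). Oxygen in flox gave 492 against at most 266 in 35 groupings, and its shared calls with KO 96 against 0 in 40, again with the real grouping the 1 as large. Chance is therefore excluded at the 0.05 level for the counts of the 4 comparisons. For the interaction and the shared counts, the regroupings also mixed the genotypes or the oxygen levels themselves. They thereby removed the separate differences on which an interaction or shared calls rest, so they cannot decide on those counts. The grouping with 2023 genes set normoxia flox 1, 2 and 3 with normoxia KO 1 and 2, which parts none of the normoxia pairs and points to a structure of the samples. The one with 2273 exchanged hypoxia flox 2 and hypoxia KO 1. That exchange sorts the hypoxia libraries by immediate early genes, at a mean log2 CPM of 9.30 to 9.58 against 6.35 to 7.98. The genotype groups in hypoxia differ from that sorting only by these libraries. Among the 24 groupings that part as many pairs as the real one, the real was again the 1 as large, and the highest other had 393. For the lists called by camera, chance is not excluded: 41 of 60 groupings called as many in normoxia (12, highest other 22), 17 of 60 in hypoxia (21, highest other 25), 34 of 35 for oxygen in flox (11, highest other 23) and 32 of 60 for oxygen in KO (14, highest other 20).

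The first pattern weighed is the lower level of arterial and smooth muscle genes in KO. Fewer cells of all other types would lower pericyte markers too, and these had a median of 1.29 higher in hypoxia KO, which argues against it. An immediate early response to dissociation would take the arterial change with it, yet with that score as a covariate the arterial median was -0.93 in normoxia and -0.97 in hypoxia. Fewer arterial segments in the KO preparations stays open: with the smooth muscle score as a covariate the arterial median went from -1.03 to -0.36 in normoxia and from -1.15 to -0.82 in hypoxia, so vessel composition and a loss of arterial identity, which the KO genotype may cause, cannot be told apart.

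The second is the rise of proliferation genes with hypoxia in flox and its absence as a large change in KO. Neural RNA in normoxia flox 4 and normoxia KO 4 is argued against, since the interaction median was -2.33 without those libraries, against -2.27. With the sex signal as a covariate it was -2.47, which argues only against a sex effect of equal size in all groups. In hypoxia the sex signal nearly follows genotype, so a sex effect particular to hypoxia cannot be told apart from genotype. Dividing cells of another type stay open, as no list of such cells rose with the proliferation genes (the highest median in flox was 0.25 ± 0.19, for lymphocyte markers), but cells of another type that divide without growing in number would not raise its markers. A biological reading, that KO endothelium already cycles in normoxia and may respond less to hypoxia, is a hypothesis found on the same data; division markers measured in sorted or labelled endothelial cells would decide it.

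The third is the rise of inflammatory and MHC class II genes in hypoxia KO. Dissociation is a candidate explanation for the inflammation list: with the immediate early score as a covariate its median went from 0.86 to 0.37 and its call ended (adjusted p = 0.626), the fold having shrunk, while 5 of its genes still passed as higher and 2 as lower. With the lymphocyte score as a covariate its median was -0.45 (adjusted p = 0.0542) and none of its genes passed, so more lymphocytes stay open for this list as well. The smooth muscle score as a covariate shrank it about as much as the immediate early score did (median 0.40, adjusted p = 0.264, none passing), so the shrinkage is not specific to dissociation. For NF-kB targets, the lymphocyte score as a covariate took the median from 0.80 to -0.37 in hypoxia KO (camera adjusted p = 0.657, 2 genes still higher). In normoxia KO it took the median from 0.75 to -0.26 (camera adjusted p = 0.882, 4 still higher). The smooth muscle score as a covariate left these medians at 0.90 in hypoxia KO (camera adjusted p = 0.000607) and 0.84 in normoxia KO (camera adjusted p = 0.0506). MHC class II genes kept a median of 3.06 with the immediate early score as a covariate, against 3.68, which argues against dissociation for them. With the sex signal as a covariate the median was 4.18, but this cannot decide on sex. In hypoxia the sex signal nearly follows genotype. Hypoxia KO 4, the only KO library there with Y-linked transcripts, was also the highest in MHC class II genes (mean log2 CPM 5.58). More lymphocytes in the KO preparations stay open for the MHC class II genes, whose median was 0.64 with the lymphocyte score as a covariate. This covariate cannot decide, because the score itself nearly follows genotype in hypoxia (mean log2 CPM -1.70 to 0.01 in flox, -0.11 to 1.89 in KO). It also took the pericyte median from 1.29 to 0.35 and so is not specific, and the smooth muscle score as a covariate left the MHC class II median at 0.76. The B cell gene Cd79a did not track Cd74: hypoxia KO 4 had 3.80 CPM of Cd79a and 272 CPM of Cd74, and hypoxia KO 3 had 7.76 and 35.0 CPM. Presentation of antigen by the KO endothelium itself was not tested and stays open.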

How the results depend on the processing

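The settings that leave out chosen libraries, use the immediate early score or block the normoxia pairs were chosen after seeing the data; the rest were chosen before the data were examined. The 9 main results (5 gene counts, 2 shared counts and Pdcd10 in both oxygen levels) stayed within 1.5 times, with Pdcd10 past the threshold, under RLE scaling, the stricter filter, the legacy fit, RPKM, the sex signal as a covariate and without the 3 libraries of mixed sex signal. The other settings moved these counts. Without a filter the calls shared by the oxygen comparisons were 57. DESeq2 called 833 genes for oxygen in flox, 617 in KO, 145 for the interaction and 241 shared. With only 2 groups per fit, which gives no interaction, oxygen in KO had 107 and the shared calls 29. The replicate block gave 1793 for genotype in normoxia, 43 for oxygen in KO, 3 for the interaction and 23 shared, and the block over normoxia pairs gave 1751. The non-endothelial component as a covariate gave 394 for oxygen in KO. Leaving out both neuron-marker libraries gave 147 shared oxygen calls. The immediate early score as a covariate gave 859 for oxygen in flox, 521 in KO and 211 shared; the same without both neuron-marker libraries gave 4801 for genotype in normoxia, 1327 and 1009 for oxygen in flox and KO, 153 for the interaction, and 3341 and 403 shared. The cause was not tested, except that fits with fewer libraries and blocks have fewer degrees of freedom by construction.

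Leaving out 1 library gave 2085 to 3645 genes for genotype in normoxia, 2664 to 4499 in hypoxia, 332 to 481 for oxygen in flox, 53 to 523 in KO and 28 to 98 for the interaction, with Pdcd10 at -1.20 to -1.02 in normoxia and -1.27 to -1.04 in hypoxia. Named genes, Pdcd10 included, lost 451 of 3139 calls in such fits and gained 7 in the 476 values not called. The lost ones did not include Pdcd10. By gene, 15 of 98 calls in normoxia, 22 of 120 in hypoxia, 15 of 40 for oxygen in flox, 30 of 41 in KO and 10 of 24 for the interaction were lost at least once. The replicate block ended 84 of 325 calls of named genes.

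Of the lists, 86 of 831 calls ended and 131 of 1059 values not called gained one when 1 library was left out. With an estimated correlation 70 of 75 calls ended, and fry ended 48 of the 75 and made 1. Some turned. Neuron markers were at 0.10 for oxygen in flox and at -0.44 in the interaction with the non-endothelial component as a covariate, and inflammation genes at -0.34 for oxygen in flox without the 3 libraries of mixed sex signal. Leaving out 1 library took the interaction of immediate early genes from -0.44 to 1.31, of barrier transporters from -0.0925 to 0.12 and of glycolysis from -0.17 to 0.26, and MHC class I for oxygen in KO from -0.19 to 0.27. The cause was not tested. In the simulated data, 2-fold changes were found in 20.9% of cases for the interaction and 1.5-fold changes in 16.4% to 26.9% for the 4 comparisons. Far fewer genes changed there than were called in the real genotype comparisons, so these rates need not hold for the real data.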

Other observations

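The lists below were fixed in advance, and the basement membrane test at the end was chosen only after the result was seen. Barrier transporters of brain endothelium shifted in both directions in KO. In normoxia 2 of 23 were higher and 6 lower (2 and 7 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.151), and in hypoxia 2 and 5 (2 and 6 adjusted over the list alone), with a median of -0.17 (adjusted p = 0.0962). The lactate transporter gene Slc16a1 changed by 0.92 ± 0.17 in normoxia. Junction genes had 5 higher and 1 lower of 19 in normoxia KO, 5 and 2 adjusted over the list alone, among them Jam2 (-0.65 ± 0.13), and 6 and 2 in hypoxia, with equal numbers adjusted over the list alone. Capillary genes had 1 of 15 higher and 5 lower at either oxygen level, with medians of -0.22 and -0.28, among them Spock2 (-0.87 in normoxia, -0.90 in hypoxia) and Itm2a (-1.14 and -1.28). Venous genes had 3 higher and 1 lower of 15 in normoxia, including Vwf, the von Willebrand factor (1.18 ± 0.24), and none higher and 4 lower in hypoxia, where the median was 0.12 and the mean 0.26 while camera pointed down (adjusted p = 0.377). None of these lists was called by camera.

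Interferon response genes had 1 of 32 higher in normoxia KO at a median of 0.16 (adjusted p = 0.165) and 8 higher in hypoxia KO, 9 adjusted over the list alone, at a median of 0.34 (adjusted p = 0.00195, adjusted p = 0.646 with an estimated correlation), with Ifit2 up by 1.23 ± 0.18 and the guanylate-binding protein gene Gbp2 by 1.47 ± 0.35. MHC class I genes had 2 of 17 higher in normoxia KO (median 0.32, adjusted p = 0.0866) and 4 in hypoxia KO, 12 adjusted over the list alone (median 0.68, adjusted p = 0.000354, adjusted p = 0.61 with an estimated correlation), with H2-D1 up by 1.18 ± 0.25. Both rises shrank without hypoxia KO 4, to 4 higher at a median of 0.18 for interferon response and to 2 higher at 0.34 for MHC class I, both still called. There H2-K1 and B2m no longer passed (adjusted p = 0.112 and 0.0528). Mesenchymal transition genes had 7 of 20 higher and 3 lower in normoxia KO (median 0.21, adjusted p = 0.165), with Fn1, the fibronectin gene, up by 1.30 ± 0.13 and Tgfb2 at -1.36 ± 0.14. The smooth muscle gene Acta2, also a member of this list, was among the lower genes there. BMP, TGF-beta and Notch targets had 3 higher and 6 lower of 25 in normoxia KO, including Smad6, an inhibitor of BMP signalling (-1.24 ± 0.14), and 4 and 3 in hypoxia KO. Wnt targets had 3 higher and 2 lower of 20 in normoxia KO and 2 and 6 in hypoxia KO, with Ccnd1, the cyclin D1 gene, up by 1.54 ± 0.18 in normoxia. Oxidative phosphorylation genes had medians of 0.03 and 0.08 in KO, and cholesterol synthesis genes -0.20 and 0.08, with no camera call. Pan-endothelial markers had 3 higher and 5 lower of 20 in normoxia KO at a median of -0.02, and 3 and 3 in hypoxia KO at -0.07.

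Among markers of other cells, Lyve1, a hyaluronan receptor gene of lymphatic endothelium and perivascular macrophages, rose by 3.66 ± 0.32 in normoxia KO and 1.57 ± 0.30 in hypoxia KO. Col3a1, a fibroblast collagen gene, rose by 2.76 ± 0.28 and 2.83 ± 0.29. The fibroblast list had 2 higher and 2 lower of 13 in normoxia KO at a median of -0.72 (adjusted p = 0.962), and 4 higher in hypoxia KO at 0.15 (adjusted p = 0.0474, adjusted p = 0.528 with an estimated correlation), a call lost without hypoxia flox 5 (median -0.01, adjusted p = 0.163). Choroid plexus markers had medians of 0.90 in normoxia KO (none of 12 passing, adjusted p = 0.0382, adjusted p = 0.823 with an estimated correlation) and 1.72 in hypoxia KO (4 higher, adjusted p = 0.0167, adjusted p = 0.61 with an estimated correlation). The first call was lost without normoxia flox 2 (adjusted p = 0.107) or normoxia KO 2 (adjusted p = 0.0931), the second without hypoxia KO 3 (adjusted p = 0.0553). In the exact permutation test the lists called here did not pass: adjusted p was 0.185 for choroid plexus markers in normoxia KO and 0.0817 in hypoxia KO, and 0.0521 for fibroblast markers, interferon response and MHC class I genes in hypoxia KO. In KO against flox, medians in normoxia and hypoxia were -0.70 and 0.23 for astrocyte, -1.15 and -0.44 for neuron, 0.63 and 1.28 for oligodendrocyte, -0.56 and 0.94 for oligodendrocyte precursor and 0.54 and 0.44 for erythrocyte markers, none called in the main fit. With the block over the normoxia pairs, camera called neuron markers lower in normoxia KO (median -0.78, adjusted p = 8.01e-06), with no member passing. In normoxia KO, neutrophil markers had 0.50 and microglia and macrophage markers -0.65 although camera pointed up, neither called, and immediate early genes had 0.81 (adjusted p = 0.0866).

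With hypoxia, camera also called further lists, all lost with an estimated correlation. In flox these were oxidative phosphorylation (-0.17, adjusted p = 8.27e-05), perivascular fibroblast markers (-1.04, adjusted p = 0.00158), smooth muscle markers (-0.49, adjusted p = 0.00184), cholesterol synthesis (-0.37, adjusted p = 0.00343), Wnt targets (0.17, adjusted p = 0.0121), neuron markers (-5.76, adjusted p = 0.0121), BMP, TGF-beta and Notch targets (-0.29, adjusted p = 0.0318) and erythrocyte markers (0.51, adjusted p = 0.0485), and their adjusted p with an estimated correlation lay between 0.368 and 0.82. Without normoxia flox 4, with its neural RNA, the oxidative phosphorylation, Wnt and neuron calls ended (adjusted p = 0.0753, 0.388 and 0.72). In KO they were pericyte markers (0.67, adjusted p = 4.01e-06), lymphocyte markers (0.79, adjusted p = 4.06e-05), oxidative phosphorylation (-0.15, adjusted p = 6.91e-05), NF-kB targets (0.41, adjusted p = 0.000222), erythrocyte markers (0.75, adjusted p = 0.00054), mesenchymal transition (0.24, adjusted p = 0.00246), neutrophil markers (2.27, adjusted p = 0.0053), hypoxia-inducible factor targets (0.11, adjusted p = 0.0312) and venous genes (-0.27, adjusted p = 0.0384), between 0.382 and 0.894 with an estimated correlation. Neutrophil markers were not called without hypoxia KO 4 (0.89, adjusted p = 0.0584).

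Since nidogen and collagen IV genes rose with hypoxia in both genotypes, basement membrane genes as a class may have risen as much as the tip cell list. The test took 21 basement membrane and collagen processing genes outside the fixed lists. Their median was 0.0058 for oxygen in flox, against 0.95 for the tip cell list, which argues against as large a rise of these 21 genes there. In KO it was 0.21 against 0.82, which leaves the question open. The nidogen and collagen IV genes that rose belong to the tip cell list, so the test cannot speak for the class as a whole. In both genotypes 5 of the 21 were higher and 1 lower. Camera did call these genes higher, in flox (adjusted p = 0.0485, 0.303 with an estimated correlation) and in KO (adjusted p = 0.000773, 0.0896 with an estimated correlation), so a smaller rise is not excluded.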
